A study of Arabidopsis thaliana with 12 samples.

How the data were processed

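Total RNA of whole Arabidopsis plantlets was sequenced as paired-end reads of 250 bp on an Illumina HiSeq 2500 in rapid mode, per the labels' protocols. There were 12 samples in 4 groups of 3, held at 0, 4, 10 and 22 °C, and groups and replicate numbers were taken from the labels. The labels of each sample give 24 h of cold, while the series text also names 48 and 72 h, and the duration per sample was taken as the labels give it. HISAT2 2.2.0, kallisto 0.42.4, edgeR and the genome build TAIR10 are named per the submitters' processing notes, and which step each tool did is not given in the sources used here. Nothing used here states whether counting took account of strand, so reads of overlapping antisense genes cannot be told apart.

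The authors deposited a table of estimated counts per transcript, which need not be whole numbers, and a table of CPM values (counts per 1000000 of a library's total) of the same transcripts. The deposited CPM values are the deposited counts scaled by each column's total, since recomputing them gave a largest difference of 5.46e-11. Each table holds 56132 transcripts. Of these, 41623 carry an annotated Arabidopsis locus (33560 loci) and 14509 are assembled transcripts in 7823 assembled loci with no map to annotated genes. The assembled transcripts held between 9.79% and 12.2% of a library's counts. Each table also has 6 columns that do not match any sample of the series and were not used. Estimated counts split reads between similar sequences by a model, so values of near-identical gene copies are uncertain.

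For the gene analysis the estimated counts of annotated transcripts were summed per locus and rounded to whole numbers. Gene names came from the NCBI annotation of TAIR10.1, in which 32818 of the loci were found, and no coordinates were taken from it. Printed CPM values of genes are scaled by edgeR's TMM factors, which lay between 0.792 and 1.19. Genes were kept by filterByExpr, which left 21293. They were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) in 1 fit of all 12 samples with 1 mean per temperature, so that all groups share an estimate of spread (common biological coefficient of variation 0.1). The p-values were adjusted by Benjamini-Hochberg per comparison, and genes with an adjusted p under 0.05 were called. The 6 comparisons were each cold temperature against 22 °C and each pair of cold temperatures, and an omnibus F test covered all 4. Standard errors of log2 fold changes were derived from the same fit, as the absolute log2 fold change divided by the square root of the test's F statistic. They are therefore approximate.

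Before the data were examined, 362 genes in 29 lists were fixed. They cover the CBF/DREB1 factors, other early cold transcription factors, CBF pathway regulators, COR/LEA genes, raffinose, starch and sucrose enzymes, proline metabolism, flavonoids, light harvesting, the Calvin cycle, chlorophyll synthesis, the clock, abscisic acid, gibberellins, cell wall expansion, aquaporins, heat shock, antioxidants, cold-shock and glycine-rich proteins, ribosome biogenesis, membrane lipids, salicylate, jasmonate, cell division, flowering time, nitrate, and markers of roots, seeds, floral organs and reference genes. Locus IDs were checked against the reference's names, and 21 were kept by hand under another name of the same gene or where the reference gives no symbol. Lists with at least 4 tested members (28) were tested with camera of limma 3.58.1 at a preset correlation of 0.01. Camera asks whether a list moves relative to other genes. A count adjusted over the list alone applies Benjamini-Hochberg to the members of 1 list. Genes named per comparison followed a rule fixed beforehand. It takes the 8 largest rises and 8 largest falls against 22 °C, and 5 and 5 between cold temperatures, among called genes with a mean of at least 5 CPM and all 3 samples of one group above the other's. It adds up to 4 members of each list by absolute log2 fold change, and CBF1, CBF2, CBF3, COR15A, RD29A, GOLS3, CCA1, LHY and TOC1. For transcript usage it takes the 5 smallest p-values per comparison and CCA1, LHY, PRR7, PRR9, TOC1 and GRP7, of which PRR7 and TOC1 did not enter the usage test. Some of these were left out for length.

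Transcript usage was tested with edgeR's diffSpliceDGE on transcript counts for genes with at least 2 transcripts past filterByExpr (4532 genes and 10529 transcripts), with dispersions from all 27262 transcripts past the filter. Of the 33560 loci, 5880 have 2 or more annotated transcripts. Dispersions from genes with several tested transcripts alone were run as an alternative, and both counts had been seen before one was chosen as the reported one.

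The chain was tested on simulated counts with known changes. All simulated genes had 1 dispersion, and a small part of them changed, in both directions. Scaling in data where most genes change was therefore not tested by it. For 0 against 22 °C (20966 genes in the simulated table) the edgeR test recovered 61.2% of the genes changed by 1.5-fold, 96.9% of those changed by 2-fold and 100% of those changed by 4-fold, with 15 false calls. The usage test recovered 99.5% of 200 changed genes among 4332, with 13 false calls. Replicates of a group differed by more than sampling noise in each of the 12 pairs (chi-square of 4.09 to 10.1 per gene over genes with more than 20 counts in the pair together). No library was therefore treated as a second sequencing of another. This check cannot tell separate pools of plantlets from repeat preparations of 1 pool. Floors for genes at 0 use 3 counts per library and cover counting error only.

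The alternatives tried were DESeq2 1.42.0's size factors, total counts alone and upper quartile factors in place of TMM, no filter or a mean of at least 5 CPM, DESeq2's own test, limma on log2(CPM + 1) and log2(CPM + 0.25) of the deposited CPM, single transcripts, only the 2 groups compared, the replicate number as a block, and each library left out in turn. For lists an estimated correlation and fry, which does not compare a list with other genes, were tried. For usage the Simes test, stricter filters and limma's diffSplice were tried. Including the assembled loci in library sizes and fit was added after seeing the data. Random lists of genes, drawn 10000 times, were set beside the light-harvesting list after seeing the data, and the matched ones took 1 of the 50 genes nearest in mean expression for each member. Unchanged groups were simulated against the 22 °C libraries to give the values that shared controls produce.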

Results

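Transcript levels were measured by paired-end RNA sequencing of whole plantlets of Arabidopsis thaliana, ecotype Columbia-0, a small flowering plant used as the standard laboratory plant. Plantlets 14 days old and raised on agar plates at 22 °C were moved to 0, 4 or 10 °C or kept at 22 °C. Each temperature had 3 libraries, and each library came from a pool of 10 plantlets. The labels of the single samples give 24 h in the cold for every temperature, whereas the text for the whole series names 24, 48 and 72 h. If those durations belonged to 0, 4 and 10 °C in turn, temperature and duration could not be separated in any comparison that involves 4 or 10 °C. Whether each temperature had a chamber run of its own is not given in the sources used here, so the p-values measure the spread between these samples.

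The deposited table gave 32870040 to 41683299 estimated counts per library. The group means were 34220528 ± 1172225 counts at 0 °C, 36809250 ± 4356916 at 4 °C, 35564739 ± 2053731 at 10 °C and 36017065 ± 3740653 at 22 °C (SD, n = 3). Between 17481 and 18917 annotated genes reached 1 CPM (here counts per 1000000 of a library's counts on annotated genes) in a library. At the smallest depth 1 count was worth 0.0346 CPM on that scale. The 10 most abundant genes held 10.7% ± 0.286 of the counts on annotated genes at 22 °C and 6.02% ± 0.0696 at 10 °C (SD, n = 3). The 12 libraries separated by temperature, with 54.1% of the variance on the first principal component and 21.3% on the second. Of 21293 genes tested, 18845 (88.5%) differed among the 4 temperatures at a false discovery rate of 0.05 (edgeR quasi-likelihood F test). In every comparison with 22 °C that follows, log2 fold changes are cold over 22 °C with the standard error after ±, and a gene named with a value passed the test unless its adjusted p is given.

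**Figure D1:**
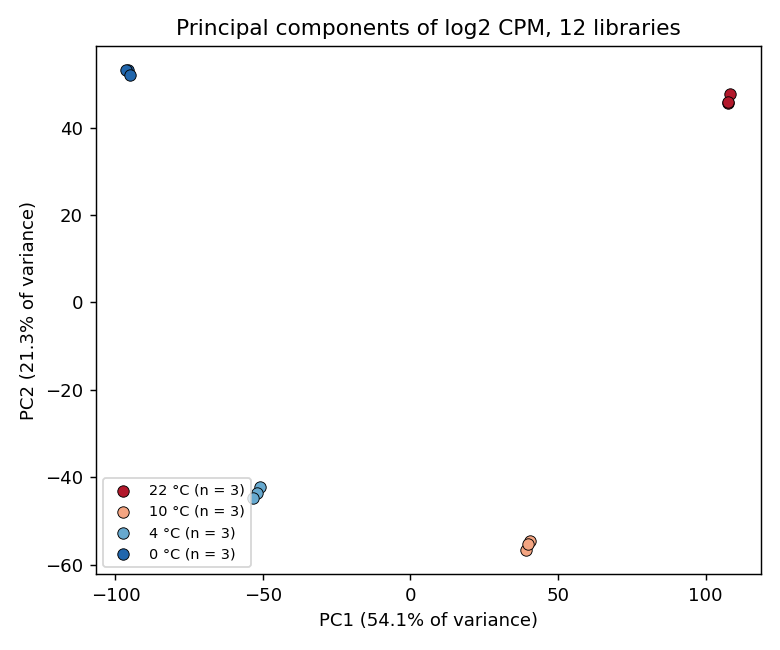
First and second principal components of log2 CPM for the 12 libraries, coloured by temperature (3 points each). The first component holds 54.1% and the second 21.3% of the variance, and the 3 libraries of a temperature lie together and apart from the other temperatures.

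The comparison of 0 with 22 °C asked which genes respond to the lowest of the 3 temperatures. CBF2 (AT4G25470), a transcription factor that binds the promoters of cold-regulated genes, stood at 140.3 ± 3.41 CPM at 0 °C against 1.51 ± 0.311 CPM at 22 °C (SD, n = 3), a log2 fold change of 6.55 ± 0.088. GOLS3 (AT1G09350), a galactinol synthase at the first committed step of raffinose synthesis, rose by 9.10 ± 0.038, from 5.1 ± 0.0786 to 2795 ± 66.5 CPM. The expansins EXPA8 (AT2G40610, -6.67 ± 0.13) and EXPA1 (AT1G69530, -6.26 ± 0.061), which loosen cell walls, were among the genes that fell most. EXPA1 went from 394 ± 6.26 CPM to 5.12 ± 0.57 CPM. The largest changes also included a rise of the late embryogenesis abundant protein gene LEA4-5 (AT5G06760, 8.54 ± 0.084) and falls of OFP16 (AT2G32100, -5.69 ± 0.12), BEE3 (AT1G73830, -5.67 ± 0.17) and BBX15 (AT1G25440, -5.39 ± 0.061), 3 genes that encode transcriptional regulators. The 3 libraries at 0 °C held no count of AT1G20430, at least 111-fold lower than at 22 °C with a floor of 3 counts per library. That floor covers counting error only, and a fall of AT1G20430 cannot be told apart from counting of its reads on assembled transcripts.

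At 0 °C each tested member of the CBF/DREB1 list, the other early cold factors and the cold-regulated genes rose, while the lists of proline metabolism and of CBF regulators were not called. All 4 tested genes of the CBF/DREB1 list rose (median 5.69, camera adjusted p = 6.19e-09), among them CBF1 (AT4G25490, 5.63 ± 0.19) and CBF3 (AT4G25480, 5.05 ± 0.099). All 13 other early cold transcription factors rose too (median 3.54, adjusted p = 2.46e-23), with the zinc finger factors ZAT6 (AT5G04340, 5.84 ± 0.089), ZAT12 (AT5G59820, 5.32 ± 0.067) and ZAT10 (AT1G27730, 5.09 ± 0.051) in front. The 20 cold-regulated and late embryogenesis genes all rose (median 5.19, adjusted p = 2.27e-70). RD29A (AT5G52310) reached 15320 ± 305 CPM from 94.2 ± 5.17 CPM (log2 7.35 ± 0.045), and COR15A (AT2G42540), whose product protects chloroplast membranes during freezing, rose by 6.50 ± 0.071. Of 16 raffinose, starch and sucrose enzymes 12 rose and 3 fell (adjusted p = 2.42e-20), led after GOLS3 by SUS1 (AT5G20830, 6.96 ± 0.34), a sucrose synthase, and BAM3 (AT4G17090, 5.86 ± 0.027), a starch-degrading amylase. Of 20 flavonoid and anthocyanin genes 16 rose and 1 fell (median 1.92, adjusted p = 2.62e-11), with MYB111 (AT5G49330, 5.16 ± 0.15), a regulator of flavonol synthesis, and UGT78D2 (AT5G17050, 4.87 ± 0.033) highest. Proline metabolism gave 4 rises and 2 falls among 7 genes, with P5CS2 (AT3G55610, 3.14 ± 0.041) higher and P5CS1 (AT2G39800, -0.70 ± 0.037) lower (adjusted p = 0.139), and its median of 0.21 turned to -0.20 with total counts alone. Regulators of the CBF genes gave 7 rises and 2 falls among 10 (adjusted p = 0.984, median 0.36, but -0.05 with total counts alone), and PIF4 (AT2G43010, -2.42 ± 0.085), a phytochrome-interacting factor, fell most. The numbers of these 7 lists were the same adjusted over the list alone, and the 5 calls among them held with an estimated correlation. There their adjusted p lay between 0.000819 and 0.00862, far above the values with the preset correlation.

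The light-harvesting, Calvin cycle, chlorophyll synthesis, cell wall expansion, aquaporin and nitrate lists were called lower at 0 °C by camera. Of 15 light-harvesting complex genes 12 fell and 1 rose, with LHCB4.2 (AT3G08940, -1.75 ± 0.042) and LHCB2.3 (AT3G27690, -1.32 ± 0.038) lowest. Their camera adjusted p was 0.00355 (adjusted p = 0.374 with an estimated correlation), and the median was -0.29, but -0.71 with total counts alone. 11 of 15 Calvin cycle genes fell and 1 rose, RCA (AT2G39730, -2.04 ± 0.19), the activase of Rubisco, by the most (adjusted p = 0.0364, and adjusted p = 0.374 with an estimated correlation). The tested transcripts of RCA together stood at 173 CPM at 22 °C and 41.5 CPM at 0 °C. A fall of RCA cannot be told apart from counting of its reads on assembled transcripts. The Calvin cycle call ended without the first library at 0 °C (adjusted p = 0.0513) or without the third (0.0507). Its alternatives ranged from 4.56e-07 with fry, which does not compare a list with other genes, to 0.374. 8 of 13 chlorophyll synthesis genes fell and 2 rose (adjusted p = 0.00221, and adjusted p = 0.106 with an estimated correlation), with CAO (AT1G44446, -2.09 ± 0.040), the enzyme of chlorophyll b synthesis, and GUN4 (AT3G59400, -1.51 ± 0.034) among the falls. Cell wall expansion genes fell in 12 of 14 cases and rose in 2 (median -1.82, adjusted p = 3.14e-07, and 0.00862 with an estimated correlation). Of 18 aquaporins, the water channels of the plasma and vacuolar membranes, 15 fell and 3 rose, with PIP2;3 (AT2G37180, -2.42 ± 0.066) low and PIP2;6 (AT2G39010, 2.05 ± 0.035) high (adjusted p = 0.000301, and adjusted p = 0.159 with an estimated correlation). Of 5 nitrate genes 4 fell and 1 rose, the falls including NRT2.1 (AT1G08090, -1.45 ± 0.12), a high-affinity nitrate transporter, and NPF6.3 (AT1G12110, -1.28 ± 0.038) (adjusted p = 0.0364, and adjusted p = 0.262 with an estimated correlation). Beside the aquaporins and nitrate genes, 9 of 11 root markers fell and none rose (adjusted p = 0.115), among them EXPA18 (AT1G62980, -2.14 ± 0.15) and CASP2 (AT3G11550, -1.23 ± 0.15). These numbers did not differ adjusted over the list alone except for 9 falls in chlorophyll synthesis.

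The circadian clock list rose in 15 of 20 cases and fell in 2 (median 1.42, adjusted p = 1.51e-08). CCA1 (AT2G46830, 3.53 ± 0.043) and LHY (AT1G01060, 3.24 ± 0.087), which peak at dawn, were both higher, as was TOC1 (AT5G61380, 1.23 ± 0.058), which peaks in the evening. The time of day of harvest did not enter the analysis, so a shift in daily phase cannot be told apart from a change of level. Of 17 genes of abscisic acid synthesis and response 15 rose and 2 fell (adjusted p = 2.55e-06), with RD29B (AT5G52300, 6.82 ± 0.057) and NCED3 (AT3G14440, 2.72 ± 0.063), a key enzyme of abscisic acid synthesis, both higher. Heat shock genes rose in 14 of 16 cases and fell in 1 (median 3.72, adjusted p = 6.49e-10), and HSP70-4 (AT3G12580) went from 17.7 ± 0.858 to 1296 ± 8.14 CPM (log2 6.19 ± 0.054). All 16 ribosome biogenesis factors rose (median 1.79, adjusted p = 5.9e-19), REIL2 (AT2G24500, 2.59 ± 0.038) and APUM24 (AT3G16810, 2.53 ± 0.040) among them. The antioxidant list had 10 rises and 3 falls among 15 genes (adjusted p = 9.57e-05), but its largest rises were ELIP2 (AT4G14690, 7.57 ± 0.061) and ELIP1 (AT3G22840, 6.98 ± 0.064), chlorophyll-binding proteins induced by light stress. These 5 calls held with an estimated correlation, where their adjusted p lay between 0.00401 and 0.0403. Cold-shock domain and glycine-rich RNA-binding genes rose in 7 of 8 cases, GRP7 (AT2G21660, 3.42 ± 0.056) most (adjusted p = 2.66e-05, and adjusted p = 0.0591 with an estimated correlation). The 6 lists had the same numbers adjusted over the list alone.

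Jasmonate genes rose in 6 of 8 cases, with the repressor gene JAZ1 (AT1G19180, 4.27 ± 0.051) highest (adjusted p = 0.0163, and adjusted p = 0.0592 with an estimated correlation). Flowering time genes rose in 5 of 8 cases and fell in 1, and SOC1 (AT2G45660, 2.05 ± 0.049), a floral integrator, was higher. Their adjusted p was 0.0346 (adjusted p = 0.0881 with an estimated correlation), and the call ended at a mean of at least 5 CPM (0.165). Its alternatives ranged from 8.42e-11 with fry, which does not compare a list with other genes, to 0.165. Of 13 reference genes 10 rose and 2 fell, UBC9 (AT4G27960, 1.73 ± 0.039) most (adjusted p = 0.0425, and adjusted p = 0.252 with an estimated correlation). That call ended with total counts alone (0.431), at a mean of at least 5 CPM (0.221) and without the first library at 22 °C (0.0532), in a range of 1.35e-09 (with fry) to 0.431. The remaining lists were not called. Salicylate defence had 5 rises and 2 falls among 10 genes (adjusted p = 0.266), with PR5 (AT1G75040, 3.03 ± 0.084) higher and ICS1 (AT1G74710, -1.83 ± 0.24), an enzyme of salicylate synthesis, lower. Gibberellin metabolism had 4 rises and 4 falls (adjusted p = 0.544), with GA2OX6 (AT1G02400, 3.19 ± 0.080), which inactivates gibberellins, higher and the growth repressor GAI (AT1G14920, -3.41 ± 0.092) lower, and its median of -0.32 (-0.74 with total counts alone) had the opposite sign to the test. Cell division had 4 rises and 7 falls among 16 genes (adjusted p = 0.447), with CYCA1;1 (AT1G44110, -1.48 ± 0.086) lowest. Membrane lipid genes had 4 rises and 6 falls among 13 (adjusted p = 0.123, median 0.02, but -0.40 with total counts alone), and DGAT1 (AT2G19450, 3.79 ± 0.038), an enzyme of oil synthesis, rose most. Of 5 floral organ markers AP1 (AT1G69120, 3.34 ± 0.55) and LFY (AT5G61850, 2.09 ± 0.42) rose (adjusted p = 0.984, median 0.02, but -0.40 with total counts alone), and the 2 tested seed storage genes, CRA1 (AT5G44120) and CRU3 (AT4G28520), both rose, in a list too short for the set test. For these 9 lists the numbers adjusted over the list alone were the same except for 5 rises among the lipid genes.

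In all, 15815 of 21293 genes (74.3%) differed between 0 and 22 °C, 7563 of them higher and 8252 lower, and 3386 and 3831 of these by at least 2-fold. The share of higher genes among the calls was 47.8% with TMM scaling, 35.4% with upper quartile factors and 27.6% with total counts alone. Against TMM, total counts alone moved the median log2 fold change of all genes by -0.41 for 0 °C, -0.14 for 4 °C and 0.15 for 10 °C, and upper quartile factors moved it by -0.23 and -0.14 for 0 and 4 °C, so each fold change is relative to that choice. Values of near-identical gene copies (LHCB1 and LHCB2, Rubisco small subunits, small heat shock proteins, KIN1 and KIN2) are less certain, because reads could be split between copies.

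**Figure D2:**
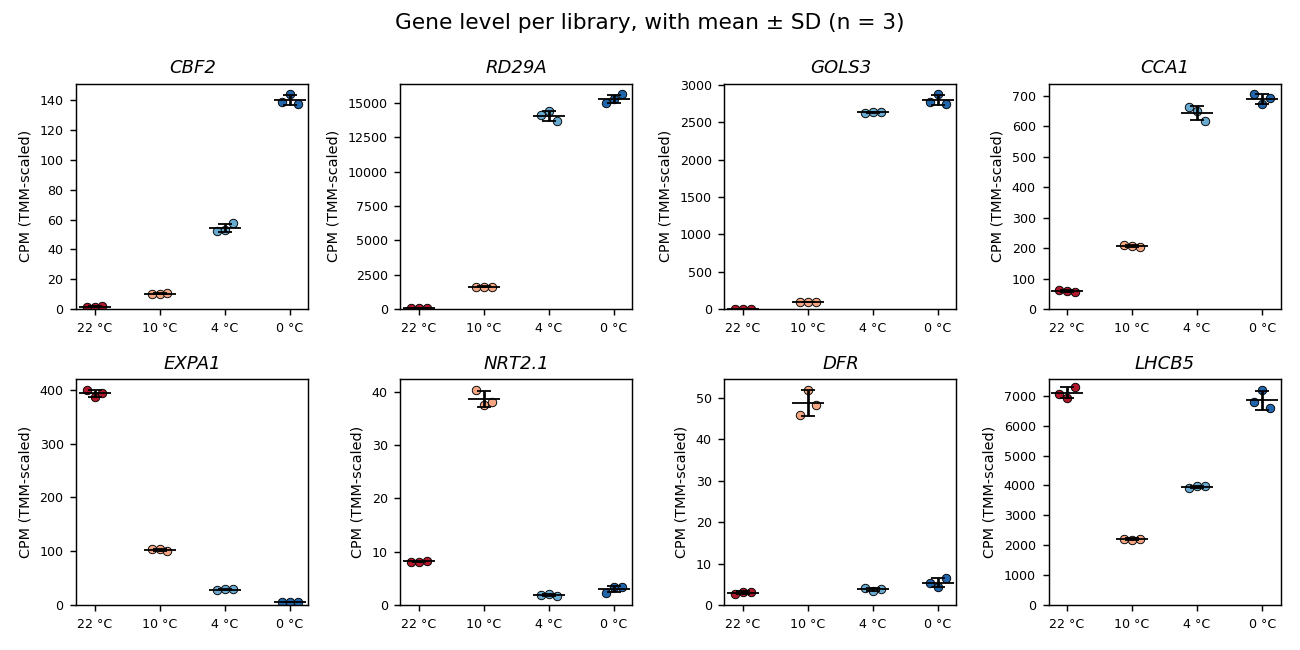
CPM (scaled by TMM) of 8 genes in each library at 22, 10, 4 and 0 °C, with points for libraries and bars for mean ± SD (n = 3). CBF2 is highest at 0 °C, EXPA1 falls from 394 ± 6.26 CPM at 22 °C to 5.12 ± 0.57 CPM at 0 °C, and NRT2.1 and DFR are highest at 10 °C.

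The comparison of 4 with 22 °C asked the same question for the middle temperature. GOLS3 rose by 9.01 ± 0.038 to 2632 ± 3.94 CPM. Flavonoid synthesis rose as a group, and the antenna genes of photosynthesis fell as a group. LHCB4.2 went from 3018 ± 66.9 CPM at 22 °C to 282 ± 7.93 CPM at 4 °C (log2 -3.42 ± 0.045, SD after ± for CPM, n = 3). EXPA8 fell by 7.57 on the log2 scale, and FRO6 (AT5G49730, -5.60 ± 0.044), a ferric reductase, and GASA6 (AT1G74670, -5.87 ± 0.11), a gibberellin-regulated gene, also fell to a small part of their levels at 22 °C. The largest rises included ELIP2 (7.94 ± 0.062), PXMT1 (AT1G66700, 7.60 ± 0.11), a methyltransferase gene, and AT1G70640 (7.53 ± 0.061). AT1G20430 was at 0 counts in the 3 libraries at 4 °C as well, at least 144-fold lower than at 22 °C with a floor of 3 counts per library. Counting of its reads on assembled transcripts cannot be told apart here either.

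All tested members rose in the CBF/DREB1 list (4 genes, median 4.93, camera adjusted p = 3.65e-07), the early factors (13 genes, 1.98, 9.15e-13) and the cold-regulated genes (20 genes, 7.69e-63). CBF2 (5.18 ± 0.088), CBF3 (5.12 ± 0.099) and CBF1 (4.73 ± 0.19) were part of the first list, and among the cold-regulated genes RD29A (7.22 ± 0.045), COR15A (6.91 ± 0.072) and KIN1 (AT5G15960, 6.10 ± 0.077) were highest. All 20 flavonoid genes rose (median 3.28, adjusted p = 1.72e-33), with F3H (AT3G51240, 5.33 ± 0.060) and FLS1 (AT5G08640, 4.83 ± 0.074), enzymes of flavonol synthesis, and CHI (AT3G55120, 4.53 ± 0.063) and 4CL3 (AT1G65060, 4.42 ± 0.066), enzymes further up the pathway, in front. Raffinose, starch and sucrose enzymes rose in 12 of 16 cases and fell in 3 (adjusted p = 3.81e-16), with BAM3 (5.29 ± 0.026) and SUS1 (5.99 ± 0.33) high. All 16 ribosome biogenesis factors rose (median 2.13, adjusted p = 1.61e-30), FIB2 (AT4G25630, 3.24 ± 0.042) and APUM24 (2.91 ± 0.040) among them. The clock (15 rose and 3 fell of 20, adjusted p = 3.94e-07), abscisic acid (15 and 2 of 17, 2.29e-05), heat shock (11 and 3 of 16, 7.74e-05) and antioxidant lists (9 and 5 of 15, 2.72e-05) were higher. Examples were CCA1 (3.42 ± 0.042), LHY (4.54 ± 0.088), RD29B (5.24 ± 0.056), CYP707A1 (AT4G19230, 4.61 ± 0.097), which degrades abscisic acid, and HSP70-4 (4.85 ± 0.051). These calls held with an estimated correlation, where their adjusted p lay between 2.56e-05 and 0.0334. Cold-shock domain and glycine-rich RNA-binding genes rose in 6 of 8 cases (adjusted p = 0.00154, and adjusted p = 0.114 with an estimated correlation). Proline metabolism rose in 4 of 7 cases and fell in 2, with P5CS2 (3.56 ± 0.042) in front (adjusted p = 0.043, and adjusted p = 0.26 with an estimated correlation). The proline call ended with total counts alone (0.096), at a mean of at least 5 CPM (0.142) and without the third library at 22 °C (0.0594). Its alternatives ranged from 8.81e-09 with fry, which does not compare a list with other genes, to 0.26. The numbers of these lists were the same adjusted over the list alone.

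All 15 light-harvesting genes fell at 4 °C (median -1.22, adjusted p = 7.38e-16), LHCB2.3 (-3.58 ± 0.042) and LHCB4.2 (-3.42 ± 0.045) most, and all 15 Calvin cycle genes fell (median -0.52, adjusted p = 1.46e-06, and adjusted p = 0.0827 with an estimated correlation), RBCS2B (AT5G38420, -2.58 ± 0.039) and CP12-2 (AT3G62410, -1.86 ± 0.061) among them. 12 of 13 chlorophyll synthesis genes fell and 1 rose (adjusted p = 7.48e-05), CHLM (AT4G25080, -1.87 ± 0.039) most. 11 of 14 cell wall expansion genes fell and 2 rose (median -1.36, adjusted p = 2.27e-10), with XTH15 (AT4G14130, -5.16 ± 0.16) low, and 14 of 18 aquaporins fell and 3 rose (median -1.34, adjusted p = 1.3e-11), with TIP2;1 (AT3G16240, -3.46 ± 0.047) lowest. The light-harvesting, chlorophyll, cell wall and aquaporin calls held with an estimated correlation, where their adjusted p lay between 0.00416 and 0.0434. 4 of 5 nitrate genes fell and 1 rose, NRT2.1 (-2.14 ± 0.12) most (adjusted p = 0.044, and adjusted p = 0.28 with an estimated correlation). That call ended at a mean of at least 5 CPM (0.0671) and without the third library at 0 °C (0.0541), 4 °C (0.0607) or 10 °C (0.053). Its alternatives ranged from 4.45e-08 with fry, which does not compare a list with other genes, to 0.28. Beside these, 4 of 11 root markers fell and 1 rose (adjusted p = 0.307). The remaining lists were not called (adjusted p from 0.119 to 0.982). Among them the test and the median had opposite signs for regulators of the CBF genes (median 0.28, but 0.15 with total counts alone), gibberellin metabolism (0.12, but -0.01) and membrane lipids (-0.17, but -0.31), and the mean and median did for jasmonate genes (0.28 and -0.41). The counts of the called lists and root markers adjusted over the list alone were the same except for 3 falling root markers.

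Between 4 and 22 °C 15739 genes (73.9%) differed, with 7735 higher and 8004 lower, and 3241 and 3487 of these by at least 2-fold. With total counts alone 6664 were higher and 9225 lower, and with upper quartile factors 6652 and 9230.

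The comparison of 10 with 22 °C asked which genes respond to mild cold. ELIP2 rose most, from 6.21 ± 0.442 to 1064 ± 26.8 CPM (log2 7.42 ± 0.061, n = 3), and GPT2 (AT1G61800, 5.95 ± 0.072), a glucose-6-phosphate transporter of plastids, came next. DFR (AT5G42800), the first enzyme of the anthocyanin branch, stood at 48.7 ± 3.14 CPM at 10 °C against 2.93 ± 0.366 CPM at 22 °C (SD, n = 3), and NRT2.1 at 38.7 ± 1.49 against 8.17 ± 0.123 CPM. CBF2 rose by 2.79 ± 0.097, CBF1 by 4.00 ± 0.20 and GOLS3 by 4.16 ± 0.034. GASA6 (-5.80 ± 0.11), BXL1 (AT5G49360, -4.66 ± 0.059), a xylosidase of the cell wall, and BBX27 (AT1G68190, -4.38 ± 0.19) were among the largest falls.

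Of 20 flavonoid and anthocyanin genes 19 rose and 1 fell (median 3.20, camera adjusted p = 1.06e-35), with PAP2 (AT1G66390, 5.74 ± 0.38), a regulator of anthocyanin synthesis, DFR (4.05 ± 0.13) and GSTF12 (AT5G17220, 3.74 ± 0.095), which is needed for anthocyanin transport, among them. Ribosome biogenesis factors rose in 15 of 16 cases (median 1.93, adjusted p = 8.96e-45), FIB2 (3.27 ± 0.042) most. 3 of 4 CBF/DREB1 genes rose (median 3.35, adjusted p = 3.95e-05), CBF3 (3.92 ± 0.10) included. Cold-regulated genes rose in 15 of 20 cases and fell in 4 (median 0.74, adjusted p = 4.02e-15), with RD29A (4.12 ± 0.039), KIN1 (4.09 ± 0.073) and COR15A (3.87 ± 0.063) highest. These 4 calls held with an estimated correlation, where their adjusted p lay between 1.99e-05 and 0.0415. 8 of 13 other early factors rose and 2 fell, with ZAT12 (1.91 ± 0.067) higher (adjusted p = 0.0127, and adjusted p = 0.127 with an estimated correlation). That call ended at a mean of at least 5 CPM (0.0511). Its alternatives ranged from 2.05e-08 with fry, which does not compare a list with other genes, to 0.127. Raffinose, starch and sucrose enzymes rose in 10 of 16 cases and fell in 4, BAM3 (2.56 ± 0.023) included (adjusted p = 5.04e-06, and adjusted p = 0.0997 with an estimated correlation). The antioxidant list had 9 rises and 5 falls among 15, with ELIP1 (5.49 ± 0.060) and ELIP2 high and CAT3 (AT1G20620, -2.07 ± 0.031), a catalase, low (adjusted p = 0.0014, and adjusted p = 0.0997 with an estimated correlation). Adjusted over the list alone these numbers were the same.

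All 15 light-harvesting genes fell at 10 °C (median -1.49, adjusted p = 4.47e-26), LHCB2.3 (-2.45 ± 0.040), LHCB4.2 (-2.02 ± 0.043) and LHCA2 (AT3G61470, -1.81 ± 0.047) among them. 16 of 18 aquaporins fell and 2 rose (median -1.08, adjusted p = 1.99e-16), TIP2;1 (-3.04 ± 0.046) and TIP2;3 (AT5G47450, -2.37 ± 0.043) most. 10 of 14 cell wall expansion genes fell and 1 rose (median -0.49, adjusted p = 5.3e-07), EXPA8 (-4.02 ± 0.10) and EXPA1 (-1.94 ± 0.045) included. These 3 calls held with an estimated correlation, where their adjusted p lay between 0.015 and 0.0271. 9 of 13 chlorophyll synthesis genes fell and 2 rose (adjusted p = 0.00446, and adjusted p = 0.155 with an estimated correlation), CHLM (-1.26 ± 0.038) most, and 10 of 15 Calvin cycle genes fell and 4 rose, with RCA (-1.70 ± 0.18) lower (adjusted p = 0.0256, and adjusted p = 0.473 with an estimated correlation). The limit given for RCA at 0 °C holds here as well. The Calvin cycle call ended with total counts alone (0.159) and at a mean of at least 5 CPM (0.0511). Its alternatives ranged from 9.32e-07 with fry, which does not compare a list with other genes, to 0.473. Root markers had 5 rises and 2 falls among 11 (adjusted p = 0.917), and nitrate genes 3 rises and 2 falls among 5 (adjusted p = 0.917), with NRT2.1 (2.24 ± 0.098) up and NIA2 (AT1G37130, -0.96 ± 0.037), a nitrate reductase, down. The clock list was not called (adjusted p = 0.145), although CCA1 (1.79 ± 0.040) and LHY (4.17 ± 0.087) were higher. The floral signal gene FT (AT1G65480) went from 1.3 ± 0.0394 to 13.7 ± 1.34 CPM (log2 3.39 ± 0.14) in a flowering list that was not called (adjusted p = 0.836). The other lists were not called either (adjusted p from 0.0832 to 0.966), and the reference genes were called with total counts alone (0.0231, in a range of 2.21e-07 with fry to 0.473). Test and median had opposite signs for regulators of the CBF genes (median 0.15, but 0.30 with total counts alone), proline metabolism (0.40), gibberellin metabolism and salicylate defence (-0.15, but 0.00 with total counts alone). The counts in this comparison adjusted over the list alone were the same except for 11 falling cell wall genes, 7 falling clock genes (6 over all genes tested), 8 rising heat shock genes (7) and 8 falling cell division genes (7).

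Between 10 and 22 °C 13763 genes (64.6%) differed, 6894 higher and 6869 lower, and 2246 and 1908 of these by at least 2-fold. The higher share was 50.1% with TMM and 61.6% with total counts alone.

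**Figure D3:**
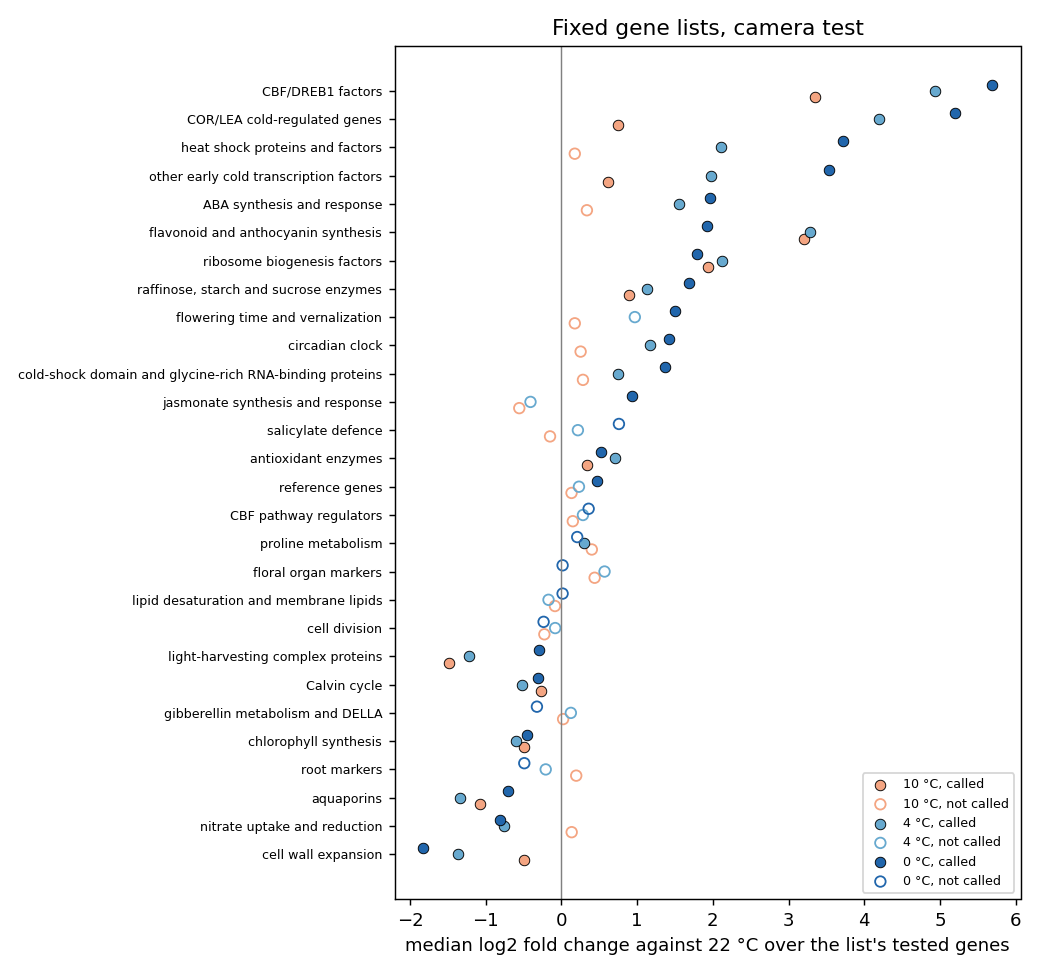
Median log2 fold change against 22 °C of 28 fixed gene lists at 10, 4 and 0 °C, with filled points where camera gave an adjusted p under 0.05. The cold-regulated genes reach a median of 5.19 at 0 °C and 0.74 at 10 °C, and the light-harvesting genes lie nearer to 22 °C at 0 °C (-0.29) than at 10 °C (-1.49) or 4 °C (-1.22), whose own difference turned from 0.27 to -0.02 with total counts alone.

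The 3 cold temperatures were also compared with each other, in the same fit of all 12 libraries. Log2 values are now the colder over the warmer temperature, and a list's count gives its genes that were higher and lower in the colder group. At 0 against 10 °C the cold-regulated genes were higher in all 20 cases (median 2.94), COR47 (AT1G20440, 5.80 ± 0.23), COR27 (AT5G42900, 5.21 ± 0.055) and ERD7 (AT2G17840, 5.07 ± 0.033) most, with GOLS3 (4.93 ± 0.030) and CBF2 (3.76 ± 0.069) also higher. EXLA1 (AT3G45970, 6.83 ± 0.063), an expansin-like gene, was among the largest rises and LBD4 (AT1G31320, -5.28 ± 0.17) and BBX15 (-5.21 ± 0.061) among the largest falls, and XTH22 (AT5G57560, 4.37 ± 0.050), a xyloglucan endotransglucosylase, was higher as well. 15 of 16 heat shock genes were higher (median 3.47), including HSP70-4 (5.08 ± 0.050), and so were all 8 cold-shock domain and glycine-rich RNA-binding genes (median 1.23, but 0.67 with total counts alone), including GRP7 (3.01 ± 0.054), and all 8 jasmonate genes (median 1.96), including JAZ1 (3.24 ± 0.047). 13 of 15 light-harvesting genes were higher at 0 than at 10 °C (median 1.12, but 0.56 with total counts alone). LHCB5 (AT4G10340) stood at 6862 ± 320 CPM at 0 °C, 2196 ± 32 CPM at 10 °C and 7103 ± 181 CPM at 22 °C (SD, n = 3). Its log2 value for 0 over 10 °C was 1.64 ± 0.032 (standard error after ±). Flavonoid genes were lower in 15 of 20 cases and higher in 4 (median -1.20), with PAP2 (-5.68 ± 0.40), PAP1 (AT1G56650, -3.49 ± 0.15) and DFR (-3.18 ± 0.12) lowest. NRT2.1 (-3.69 ± 0.11), FT (-3.33 ± 0.14) and EXPA18 (-2.86 ± 0.14) were lower, and 9 of 11 root markers were lower and 1 higher. Adjusted over the list alone these list counts were the same except for 16 lower flavonoid genes. In total 15023 genes differed, 7225 higher and 7798 lower at 0 °C, and the higher share of 48.1% became 35.2% with upper quartile factors and 19.9% with total counts alone.

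At 4 against 10 °C all 4 CBF/DREB1 genes (median 1.71), all 13 other early factors (median 1.29) and all 20 cold-regulated genes (median 2.80) were higher. ADH1 (AT1G77120), alcohol dehydrogenase, went from 39.4 ± 1.51 CPM at 10 °C to 1384 ± 12.2 CPM at 4 °C (log2 5.13 ± 0.032, n = 3), and GOLS3 (4.85 ± 0.030), COR47 (4.48 ± 0.22) and LTI30 (AT3G50970, 3.56 ± 0.052), a dehydrin gene, were higher. 11 of 16 heat shock genes were higher, HSP90-1 (AT5G52640, 4.14 ± 0.053) and HSP70-4 (3.74 ± 0.048) among them. Flavonoid genes went both ways, with 13 higher and 7 lower, MYB12 (AT2G47460, 3.87 ± 0.084), a flavonol regulator, among the first and DFR (-3.69 ± 0.13) and LDOX (AT4G22880, -3.09 ± 0.14) among the second. NRT2.1 (-4.39 ± 0.12) and EXPA8 (-3.55 ± 0.16) were lower, 10 of 14 cell wall genes were lower and 2 higher (median -0.82), and 8 of 11 root markers were lower. The light-harvesting genes gave 9 higher and 5 lower, with a median of 0.27 that turned to -0.02 with total counts alone, and LHCB2.2 (AT2G05070, -1.54 ± 0.034) was lower. Adjusted over the list alone these list counts were the same except for 12 higher heat shock genes. In total 12764 genes differed, 6318 higher and 6446 lower at 4 °C, and the higher share of 49.5% became 37.7% with upper quartile factors and 24.1% with total counts alone.

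At 0 against 4 °C XTH22 went from 13.3 ± 0.806 CPM at 4 °C to 378 ± 5.17 CPM at 0 °C (log2 4.83 ± 0.052, n = 3), and EXLA1 (4.50 ± 0.053) was higher too. GBSS1 (AT1G32900), a starch synthase, went from 543 ± 11.9 to 25.7 ± 0.595 CPM (log2 -4.40 ± 0.034), and PCC1 (AT3G22231, -5.67 ± 0.21) fell most among the named genes. Flavonoid genes were lower in 15 of 20 cases and higher in 5 (median -1.50), including F3'H (AT5G07990, -4.29 ± 0.10), 4CL3 (-3.29 ± 0.062), CHS (AT5G13930, -2.01 ± 0.035), chalcone synthase, and PAP2 (-3.36 ± 0.43). All 15 light-harvesting genes (median 0.87) and 12 of 15 Calvin cycle genes (median 0.38, but 0.11 with total counts alone, 2 lower) were higher at 0 than at 4 °C, LHCB2.3 (2.25 ± 0.040) and RBCS2B (2.08 ± 0.038) among them. 14 of 16 heat shock genes were higher and 1 lower (median 1.95), the higher including HSFA2 (AT2G26150, 3.94 ± 0.23), a heat shock factor, and 7 of 8 jasmonate genes were, including LOX2 (AT3G45140, 2.32 ± 0.055) and JAZ1 (1.57 ± 0.044). CBF2 (1.36 ± 0.060) and CBF1 (0.90 ± 0.13) were higher at 0 °C. Cold-regulated genes were higher in 14 of 20 cases and lower in 3 (median 0.56, but 0.28 with total counts alone), with ERD7 (1.75 ± 0.028) higher and COR15A (-0.41 ± 0.055) lower. 6 of 11 root markers were lower and 3 higher, beside 13 of 18 aquaporins that were higher and 3 lower, TIP2;1 (1.93 ± 0.045) among them. Adjusted over the list alone these list counts were the same except for 14 higher aquaporins and 7 lower root markers. In total 12334 genes differed, 6210 higher and 6124 lower at 0 °C, and the higher share of 50.4% became 41.2% with upper quartile factors and 26.2% with total counts alone.

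Genes were then sorted by their calls at the 3 cold temperatures. Against 22 °C 4337 genes (20.4%) were higher and 4241 (19.9%) lower at all 3, of which 1147 and 1004 by at least 2-fold at each. Of the genes tested, 903, CBF2 and BAM3 among those singled out after the values were seen, were higher at every step from 22 to 10 to 4 to 0 °C with each step called, and 484 genes, EXPA1 likewise, were lower at every step. Fold changes against 22 °C correlated across genes between 0 and 4 °C (r = 0.80, covariance 1.73), 0 and 10 °C (r = 0.55, covariance 0.854) and 4 and 10 °C (r = 0.74, covariance 1.04). Genes are not independent replicates, and these comparisons share the 3 libraries at 22 °C. In 20 simulations of unchanged groups against the same libraries r was 0.44, 0.443 and 0.45, with covariances of 0.0372, 0.0368 and 0.0366. Genes higher in both numbered 6078 for 0 and 4 °C, 4513 for 0 and 10 °C and 5389 for 4 and 10 °C, against 2747, 2449 and 2504 for independent lists. Genes lower in both numbered 6264, 4514 and 5378, against 3102, 2662 and 2582. The simulations averaged 0.05 genes lower in both for 0 and 4 °C and 0 for each other overlap. The covariances lay 1.70, 0.817 and 1.00 above the simulated ones, which argues against shared controls as the main source of the correlations. The simulated groups held no changed genes, so their overlaps do not size what shared controls add among changed genes. The 3 control libraries cannot be split into parts of at least 2, so part of the excess in overlaps may come from the shared controls.

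Transcript usage, the share of each tested annotated transcript among those of its gene, was tested for 4532 genes with at least 2 tested transcripts. Assembled transcripts were not part of these shares, so reads counted on them at some temperatures could change a share or a gene's level. It changed in 1257 genes at 0 °C, 1152 at 4 °C and 595 at 10 °C against 22 °C (edgeR, gene-level F test), in 375 of them at all 3. For 221, 179 and 123 of these genes the total level was not called. With the Simes test usage changed in 673, 583 and 259 genes at 0, 4 and 10 °C. A mean of at least 5 CPM gave 567 at 0 °C and 612 at 4 °C, and transcripts with at least 10% of their gene's counts gave 773 at 0 °C. AT1G16840 gave the smallest p at 0 °C (adjusted p = 1.05e-19), its transcript 4 going from 3.08% ± 0.656 at 22 °C to 31.2% ± 2.21 at 0 °C (SD, n = 3). The catalase gene CAT2 (AT4G35090) raised transcript 2 from 0.713% ± 0.0785 to 5.61% ± 0.506 (adjusted p = 1.4e-15), and FUS5 (AT1G02090) raised transcript 3 from 11.4% ± 2.36 to 51.6% ± 1.48 (adjusted p = 2.63e-12). At 4 °C the transcript 3 of RCA held 29.4% ± 9.79 against 99.1% ± 0.175 at 22 °C (adjusted p = 6.96e-16). At 10 °C transcript 2 of HEME1 (AT3G14930), a gene of tetrapyrrole synthesis, held 64.9% ± 0.984 against 27.5% ± 1.81 (adjusted p = 4.63e-13). Of the clock genes, LHY moved transcript 2 from 6.10% ± 5.76 at 22 °C to 46.4% ± 6.8 at 0 °C (adjusted p = 1.37e-05) and 35.4% ± 4.7 at 4 °C (adjusted p = 7.82e-05, but 0.199 with limma, in a range of 4.03e-07 to 0.199), and was not called at 10 °C (adjusted p = 0.463). PRR9 (AT2G46790) was called at 0 °C (adjusted p = 0.00839), 4 °C (7.69e-06) and 10 °C (0.000176), and at 0 °C no longer without the first (0.0674) or second library at 22 °C (0.0514) or with the Simes test (0.0945), in a range of 0.000815 to 0.0945. CCA1 was not called (adjusted p = 0.654, 0.417 and 0.456 at 0, 4 and 10 °C), and neither was GRP7 (0.449, 0.225 and 0.709), except at 4 °C without the first library at 22 °C (0.0389, in a range of 0.0389 to 0.88).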

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

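All tests below on the light-harvesting genes, with their margin of 2 standard errors, and on genes at 0 counts were chosen only after the result was seen, and those with random lists replaced a planned one that had set the light-harvesting median against the quartiles of single genes (-0.504 and 1.08).

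A group of 2260 genes was called in opposite directions at 0 and at 10 °C against 22 °C, with the direct difference between 0 and 10 °C also called. Of these, 1175 were higher at 0 °C and lower at 10 °C, and 1085 were lower at 0 °C and higher at 10 °C. Changes of any size count here, so the numbers depend on the scaling. Total counts alone moved the median log2 fold change of all genes by -0.41 at 0 °C and 0.15 at 10 °C. The group was not counted again under another scaling than TMM. In counts that the reported tests of annotated genes did not use, 4203 of 7258 tested assembled loci differed between 0 and 22 °C, 2458 of them higher and 1745 lower. The assembled locus MSTRG.1866 stood at 27190 ± 848 CPM at 0 °C, 18630 ± 586 CPM at 4 °C, 1523 ± 44.1 CPM at 10 °C and 599.8 ± 24.7 CPM at 22 °C (SD, n = 3). Its log2 fold change between 0 and 22 °C was 5.50 (edgeR, adjusted p = 7.28e-15), and it was not tied to an annotated gene here.

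The light-harvesting genes fell at 10 and 4 °C, yet at 0 °C they stood above their level at 10 °C by a median of 1.12 on the log2 scale over 15 genes. Scaling alone is argued against, since the lowest median under 3 other scalings was 0.556, above 2 times the largest standard error of a member (0.265). Reads shared between near-identical copies are argued against as well, since the 9 members that are not LHCB1 or LHCB2 copies had a median of 1.35. A smaller fall at 0 °C shared by all genes that fell at 10 °C is argued against by the other genes at least 2-fold lower at 10 °C. Of these 1896 genes 47.2% were higher at 0 than at 10 °C, against 13 of 15 here. Of 10000 random lists of 15 of those genes, 107 had a median as high. Random genes were drawn independently, while the light-harvesting genes were correlated (estimated correlation 0.566 for 10 against 22 °C). The share of random lists may therefore be too small. A smaller fall shared by abundant genes may account for the pattern, since 5033 of 10000 random lists matched on mean expression had a median as high, while a response of the antenna genes to temperature itself and a difference in duration between groups stay open and untested.

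In 5 annotated genes (AT1G20430, AT2G44130, AT3G56160, AT1G18000 and RVE8), singled out after their values were seen, all 3 libraries of at least 1 cold group held 0 counts although the mean at 22 °C was at least 5 CPM. RVE8, a clock gene, was at least 99.9-fold lower at 4 than at 22 °C with a floor of 3 counts per library, and stood at 0.553 ± 0.654 CPM at 0 °C (SD, n = 3). Lower depth is argued against, since the lowest count expected in any of those libraries at the 22 °C level was 121.9. Counting of the reads on assembled transcripts cannot be told apart for all 5, because no map ties assembled transcripts to genes. A fall of the transcripts with temperature may also remain. By the edgeR test 4 of the 5 were not called between 10 and 22 °C, which does not show an unchanged level. RVE8 stood at 4.47 CPM at 10 °C against 9.49 CPM at 22 °C (adjusted p = 0.0628), and AT3G56160 at 3.20 against 5.65 CPM (0.493). AT1G18000 (4.78 against 5.94 CPM) and AT1G20430 (12.8 against 13.7 CPM) lay nearer to their 22 °C levels, and AT2G44130 was already at 0 counts at 10 °C. The level of RVE8 at 0 °C, whose SD exceeds its mean, does not decide whether the transcripts fell.

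Other splits of the samples were counted for each comparison. The 6 samples of a pair of temperatures make 10 splits, too few for a share under 0.05. For genes the real split, the only 1 of 10 with so large a count in each comparison, gave 15815, 15739 and 13763 calls for 0, 4 and 10 against 22 °C. It gave 15023, 12764 and 12334 for 0 against 10, 4 against 10 and 0 against 4 °C. The highest of the other splits with edgeR was 1 for 4 against 10 °C and 0 for each other comparison, where those 54 splits had 158 to 800 genes at an unadjusted p under 0.05. For lists the real values were 20, 18 and 12 at 0, 4 and 10 °C and the highest others 14, 15 and 9, and for transcript usage they were 1257, 1152 and 595 and the highest others 7, 12 and 10. Camera at the preset correlation thus called lists in splits where edgeR called no gene. Each other split mixed the temperatures unevenly, so part of the real difference stayed between its groups. These list calls therefore cannot show how many of camera's calls are false. For the 4 temperatures together the real split gave 18845 genes and the highest other 5280. Of 100 splits drawn, the real one included, it was the only 1 with so many, which argues against chance. Such splits cannot tell temperature from a chamber run of its own.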

How the results depend on the processing

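Including the assembled loci, and estimating usage dispersions from genes with several tested transcripts alone, were the only alternatives chosen after the result was seen.

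The counts of genes called between temperatures stayed within 1.5 times of the reported ones under each alternative. They ranged from 11759 to 17145 for 0 against 22 °C, 11894 to 16045 for 4 against 22 °C and 11006 to 14326 for 10 against 22 °C. Between cold temperatures they ranged from 11395 to 17463 (0 against 10 °C), 10093 to 14621 (4 against 10 °C) and 9872 to 14187 (0 against 4 °C), and for the 4 temperatures together from 13738 to 19804. With 1 library left out, the ranges in the same order were 15139 to 16005, 15028 to 15903, 12890 to 13978, 14290 to 15196, 11709 to 12898, 11537 to 12448 and 18493 to 18842. Only the 2 groups compared gave no value for the 4 temperatures together. Each of the 172 pairs of a gene and a comparison named with a fold change kept its direction and its side of the threshold without each library and under each alternative that tested it, which a mean of at least 5 CPM did for 165 of them. On log2(CPM + 1), whose pseudocount shrinks changes from low levels, the fold changes of CBF1 against 22 °C, PAP2, AP1, LFY, PCC1 and XTH15 were over 1.5 times smaller.

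Lists and usage moved more. With an estimated correlation 11 lists were called at 0 °C and 7 at 10 °C, and fry, which does not compare a list with other genes, called 23 at 10 °C. With fry, gibberellin metabolism (adjusted p = 0.00329) and cell division (0.0294) at 4 °C had the opposite direction to the test with camera, and the cause was not tested. Over all alternatives the lists called ranged from 11 to 28 at 0 °C, 14 to 27 at 4 °C and 7 to 23 at 10 °C, and without 1 library from 19 to 20, 17 to 18 and 12 to 12. Of the alternative fits of single lists, 28 ended a call, 27 made one and 441 kept the side and direction, and without 1 library 7 ended a call. Of the 27 calls made, 26 came from fry, which asks another question than camera. For transcript usage the Simes test called 673, 583 and 259 genes at 0, 4 and 10 °C, and a mean of at least 5 CPM, which tests fewer transcripts, called 567 at 0 °C and 612 at 4 °C. Transcripts with at least 10% of their gene's counts gave 773 at 0 °C. The ranges over alternatives were 567 to 1242, 583 to 1306 and 259 to 811, and without 1 library 1060 to 1268, 938 to 1175 and 419 to 587.

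Nothing in the labels says that a replicate number marks a shared plate or day, and the numbers did not pair the samples. Deviations of same-numbered samples from their group means correlated between -0.042 and 0.099, and 4 of the 12 samples matched their own number best. With the replicate number as a block 15686, 15592 and 13565 genes were called at 0, 4 and 10 against 22 °C. The block gave 14868, 12502 and 12122 between cold temperatures, 18656 for the 4 together, 19, 18 and 12 lists and 1168, 1056 and 530 genes with changed usage. The block ended the call of flowering time genes at 0 °C (adjusted p = 0.0516, in a range of 8.42e-11 with fry to 0.165) and no other list or named gene. In simulated data for 0 against 22 °C small changes were missed more often, since 61.2% of the genes changed by 1.5-fold were recovered, against 96.9% at 2-fold. The simulated genes had 1 dispersion and few changes, so the limit in the real data may differ. How far depth, and how far the number of libraries and the spread between them, set this limit was not tested.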

Other observations

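The tests of terms, and the choice of the genes named here, were made only after the result was seen.

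The genes called in opposite directions at 0 and 10 °C were tested for functional terms of the reference annotation, each direction against the background and not against the other. Both groups of genes rest on TMM scaling, and the terms were not tested under another scaling. The test was a one-sided Fisher's exact test over 266 terms with at least 10 genes, among 13164 tested genes that carry a term. Genes higher at 0 °C and lower at 10 °C (755 with a term) held 16 of 91 genes of defence against bacteria, against 5.22 in a random draw (adjusted p = 0.0142). They also held 12 of 60 genes of defence against fungi (3.44 in a random draw, adjusted p = 0.0154), 12 of 62 of the response to wounding (3.56, adjusted p = 0.0154) and 12 of 73 of the response to water deprivation (4.19, adjusted p = 0.0449). Genes lower at 0 °C and higher at 10 °C (698 with a term) held 19 of 109 genes of transmembrane receptor kinase signalling (5.78, adjusted p = 0.00107), 8 of 23 of cell wall loosening (1.22, adjusted p = 0.00192) and 10 of 50 of growth along 1 axis (2.65, adjusted p = 0.0163). Beside these terms, 9 of 11 root markers were lower and 1 higher at 0 than at 10 °C, and the terms were not tested apart from root genes.

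Of the 20 genes of the flavonoid list 13 were higher and 7 lower at 4 than at 10 °C by the edgeR test. Values of 6 of them are given here, the first 3 higher at 4 °C and the last 3 higher at 10 °C, and no test set steps of the pathway against each other. Chalcone synthase (CHS) stood at 2727 ± 53.8 CPM at 4 °C, 1445 ± 56.3 CPM at 10 °C and 676 ± 17.3 CPM at 0 °C, against 132 ± 3.84 CPM at 22 °C (SD, n = 3). Flavanone 3-hydroxylase (F3H) stood at 1080 ± 33.1 CPM at 4 °C, 326 ± 6.37 CPM at 10 °C and 275 ± 16.6 CPM at 0 °C. Flavonol synthase (FLS1) stood at 572 ± 3.45, 222 ± 4.2 and 169 ± 10.3 CPM at the same temperatures. Dihydroflavonol reductase (DFR), the first step of the anthocyanin branch, stood at 3.75 ± 0.347 CPM at 4 °C, 48.7 ± 3.14 CPM at 10 °C and 5.38 ± 1.01 CPM at 0 °C. The anthocyanin regulator PAP2 stood at 1.6 ± 0.309, 7.95 ± 0.798 and 0.152 ± 0.104 CPM, and leucoanthocyanidin dioxygenase (LDOX) at 4.71 ± 0.493, 40 ± 2.33 and 9.24 ± 1.26 CPM.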
